A study of Homo sapiens with 4 samples.

How the data were processed

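RNA of U2OS cells, a human osteosarcoma line, was hybridised to the Affymetrix Human Transcriptome Array 2.0, 1 array per sample. The series text calls the samples biological replicates, and 4 arrays were analysed: 2 of cells given the solvent DMSO and 2 of cells given nocodazole, a drug that depolymerises microtubules. Per the labels' protocols, cells were synchronised with 24 h of serum starvation and 24 h of thymidine, released into drug-free medium for 3 h and then treated for 48 h. Per the same protocols, 100 ng of total RNA was reverse transcribed, made double-stranded and amplified by in vitro transcription. The sample titles also carry the name PLKO.1, which the labels do not explain.

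The deposited values are log2 expression per row, most rows being transcript clusters, with 1 column per array. The submitters' processing notes name Partek 7.0, RMA (robust multi-array average) and the build hg19, and the settings of background correction, normalization and summarization are not given in the sources used here. The log base was taken from RMA and from the range of the values, 0.50 to 14.3. The deposited columns do not share 1 distribution. Over the genes tested, the array medians were 6.38 and 6.06 for DMSO replicates 2 and 3, and 5.87 and 5.68 for nocodazole replicates 2 and 3. The number of arrays limits the precision of every value. The median of 23 antigenomic background rows, 3.72 to 4.81 per array, was taken as the background of that array.

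The table held 65535 rows, of which 1530 were control rows and were left out of the gene tests. Of the other 64005 rows, 21771 had 1 gene symbol in the platform annotation, 1328 had several and 40906 had none. Rows with exactly 1 symbol were kept, and for the 288 genes with more than 1 row the row with the highest mean over the 4 arrays stood for the gene, which left 21469 genes, 16159 of them coding for protein. Symbols of 19683 gene rows were looked up by Entrez identifier in a RefSeq gene table, and 0 changed. The table held 777 transcript cluster rows of chromosome 20, against 2666 of chromosome 19. It held 0 of chromosomes 21 and 22, so transcript clusters of these chromosomes could not be analysed. No coordinates are given, since the gene table and the build named in the processing notes differ.

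The test was limma's moderated t (lmFit and eBayes with a trend of variance with level; limma 3.58.1 in R 4.3.3), two-sided, on the deposited values of all 4 arrays without a block, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Error terms of fold changes are limma's standard errors (SE), and those of group means are standard deviations (SD, n = 2). The design, the gene lists, the rule for named genes and the alternatives not named as added later were chosen before the data were examined. Changes are nocodazole minus DMSO on the log2 scale.

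After the arrays' medians were seen to differ, a stricter reading was added. A gene is described as having risen or fallen where its adjusted p was under 0.05 in the same direction both on the deposited values and after quantile normalization of the 4 arrays (limma's normalizeQuantiles), except where it lay below background on all 4 arrays. Unless another scale is named, a gene's log2 fold change and adjusted p are those after quantile normalization, so that they are relative to the array-wide shift. Median centring of each array over all non-control rows was a further scale.

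The steps were tested on simulated data drawn for the 21469 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale and the deposited arrays' value distributions imposed. The changed genes were all at or above the median level, and noise was drawn independently for each gene and array. Recovery of changes in dim genes was therefore not tested. Quantile normalization recovered 96% of the changes of 1 and 100% of the changes of 2, with 21 unchanged genes called. The values as imposed gave 87% and 100%, with 6950 unchanged genes called, and median centring gave 78% and 98%, with 28. With those distributions and no changed gene, 6958 genes were called lower and 1 higher.

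Gene lists were tested with limma's camera against all other genes, with a preset correlation of 0.01, two-sided, adjusted over the 35 lists with at least 5 measured genes. Camera with the correlation estimated per list and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the number of arrays, and with a preset one from the number of genes. With 4 arrays the estimated form has little power, and the small p-values of the preset form rest on the number of genes. A list is described as having risen or fallen where camera passed 0.05 in the same direction on the deposited, the quantile-normalized and the median-centred values. The lists were SASP cytokines and chemokines, SASP proteases and protease inhibitors, SASP growth factors and binding proteins, SASP shed receptors and surface proteins, NF-kB targets, p53 targets, p53-linked long non-coding RNAs, BCL2 family, G2/M and mitotic, DNA replication and S-phase, homologous recombination and Fanconi, senescence-lowered nuclear, replication-dependent histone, tubulin, alpha- and beta-tubulin, YAP/TEAD targets, SRF/MRTF and cytoskeletal, collagen and extracellular matrix, cholesterol biosynthesis, interferon-stimulated, autophagy, lysosomal, immediate-early and AP-1, unfolded protein and ATF4 response, heat shock, NRF2 targets, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein, ribosome biogenesis and MYC targets, small nucleolar RNA and microRNA genes. Osteoblast-lineage, epithelial, haematopoietic and endothelial markers stood for cell types a culture could hold. Lists overlap: GDF15 is among the growth factors and the p53 targets, TGFB2 among the growth factors and the YAP/TEAD targets, BCL2A1 among the NF-kB targets and the BCL2 family, and the alpha- and beta-tubulins are part of the tubulins. The histone list was taken by symbol prefix and also holds H1-10 and pseudogenes. For the size of a shift, list medians after quantile normalization were set against 10000 random lists of the same size. These were drawn from 20 bins of expression level, and the microRNA genes were left out of this step.

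Named genes followed a fixed rule. It took CDKN1A, MDM2, GDF15, LMNB1, HMGB2, MKI67, CCNB1, PCNA, IL6, CXCL8, IL1A, IL1B, CCL2, MMP1, MMP3, TUBB, TUBA1B, CCN1 and CCN2 whatever their values; some genes are not reported here. It added the 8 largest rises and the 8 largest falls among genes past the threshold on the deposited values, with separated groups, a mean level at or above the median and a symbol that is not a locus, antisense or small RNA name. For each list past camera it took the 2 members past the threshold with the largest change in the list's direction and the 1 with the largest change against it. Genes named outside this rule are said to be so where they appear.

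Alternatives were the replicate number as a block, each array left out, quantile normalization, median centring, dim genes left out, the mean of all rows of a gene, eBayes without trend or with a robust prior, a per-gene two-sample test without moderation of the variance, and stricter thresholds. Added after the data were seen were quantile normalization with the block or without dim genes, cyclic loess normalization, and every count of genes past the threshold on both scales. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.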

Results

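Gene expression was measured on 4 arrays of U2OS cells, a human osteosarcoma line, 2 from cells treated with the solvent DMSO and 2 from cells treated with nocodazole for 48 h after synchronisation. Nocodazole depolymerises microtubules and holds cells in mitosis, and cells that leave such an arrest without dividing are said to have slipped. The series title gives the question: whether cells after slippage express factors of the senescence-associated secretory phenotype (SASP), the set of cytokines, proteases and growth factors that senescent cells secrete. 1 comparison follows from this design, nocodazole against DMSO.

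With nocodazole, 7 of 27 measured SASP cytokine and chemokine genes rose, as did the matrix metalloproteinase genes MMP1 and MMP3. The G2/M and mitotic genes and the DNA replication and S-phase genes fell as lists (adjusted p = 0.152 with an estimated correlation for both), and 4 of 62 and 0 of 48 of their members fell on their own. CXCL8, which encodes the neutrophil chemokine interleukin-8, rose by a log2 fold change of 4.35 ± 0.19 after quantile normalization (SE, n = 2 per group; limma adjusted p = 0.000478), a 20.4-fold change. As deposited its log2 fold change was 3.87. IL1B and IL1A, which encode the proinflammatory cytokines interleukin-1 beta and alpha, rose by 2.77 ± 0.14 and 3.01 ± 0.17. LMNB1, which encodes the nuclear lamina protein lamin B1, had a log2 fold change of -1.14 ± 0.11 (limma adjusted p = 0.0116), and MKI67, which encodes the proliferation marker Ki-67, one of -1.09 ± 0.14 (limma adjusted p = 0.0374). CDKN1A and MDM2, 2 targets of p53, did not pass the test.

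On the values as deposited, limma called 5392 of 21469 genes at an adjusted p under 0.05, 51 higher and 5341 lower with nocodazole, and 28 and 399 of these changed at least 2-fold. The median change of all genes was -0.45, and it was -0.42 over 155 ERCC control rows, which match no human gene, and 0.07 over the 4 hybridisation spike controls. After quantile normalization, which moved the median of all genes to 0.00, limma called 62 genes, 41 higher and 21 lower, so the share of higher genes went from 0.946% to 66.1%. Median centring left 19 higher genes and 1 lower, a share of 95%. Both the deposited and the quantile-normalized values called 53 genes, 32 higher and 21 lower, of which 17 and 1 also passed after median centring. Without a trend of variance with level, limma called 10 genes after quantile normalization and 1 on both scales, which is 1 of the 53; with the replicate number as a block it called 37 on both scales, 34 of them among the 53. With any 1 of the 4 arrays left out, limma called 0 genes on both scales. In those fits 1 group is a single array, so the spread comes from the other group alone. Of the 53 genes, which were chosen on all 4 arrays, 50, 52, 46 and 46 kept an unadjusted p under 0.05 on both scales without DMSO replicate 2, DMSO replicate 3, nocodazole replicate 2 and nocodazole replicate 3, where 843, 725, 498 and 638 of all genes did so. On at least 1 array 9 of the 53 lay below the median of that array's background control rows, 6 of them on both DMSO arrays and 1 on all 4, so that their fold changes are not exact.

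**Figure D1:**
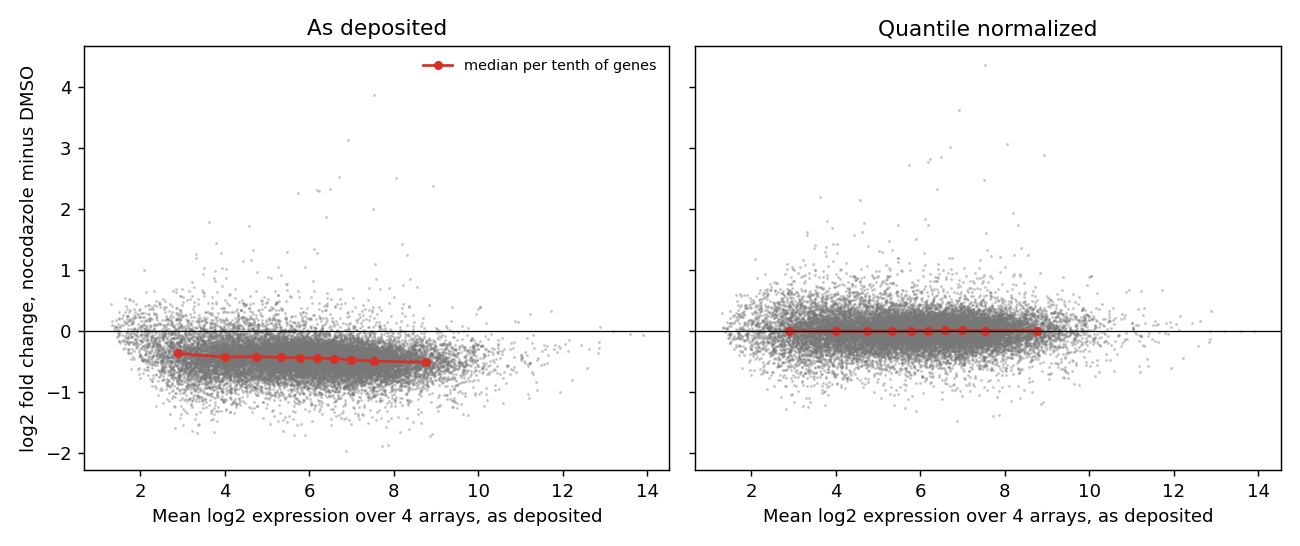
Log2 fold change of each gene (nocodazole minus DMSO) against its mean log2 expression over the 4 arrays, as deposited and after quantile normalization, with 1 grey point per gene and red points at the medians of 10 bins of genes by level. As deposited the red points run from -0.37 to -0.51, and after quantile normalization they lie within 0.01 of 0.

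The SASP cytokines and chemokines rose as a list. Of 27 measured members, 7 were called higher and 1 lower as deposited. On both scales 7 rose (CXCL8, CCL20, IL1A, IL1B, CCL2, and CCL3 and CXCL3, these last named after their values were seen), 0 fell and 20 did not pass after quantile normalization; 10 were higher and 0 lower when adjusted over the list alone. The list's median log2 fold change was 0.36. Relative to all genes it was 0.38 as deposited, and it moved to 0.59 without DMSO replicate 2, 0.26 without DMSO replicate 3 and 1.71 without dim genes. Camera gave an adjusted p of 4.65e-29 as deposited and 1.40e-15 after quantile normalization, with adjusted p = 0.152 with an estimated correlation. CXCL8 had a mean log2 expression of 5.36 ± 0.30 with DMSO and 9.72 ± 0.29 with nocodazole (SD, n = 2). CCL20, a chemokine of lymphocytes and dendritic cells, went from 5.12 ± 0.69 to 8.73 ± 0.00, a log2 fold change of 3.61 ± 0.28 (limma adjusted p = 0.00379). IL1A went from 5.21 ± 0.31 to 8.22 ± 0.06 (limma adjusted p = 0.00103) and IL1B from 4.82 ± 0.05 to 7.59 ± 0.02 (limma adjusted p = 0.000598). CCL2, which draws monocytes, went from 7.45 ± 0.29 to 9.19 ± 0.15, a log2 fold change of 1.74 ± 0.16 (limma adjusted p = 0.00946). IL6, a much studied SASP cytokine, had a log2 fold change of 0.62 ± 0.17, which did not pass (limma adjusted p = 0.262). IL6 was dim, with deposited means of 5.06 with DMSO and 5.26 with nocodazole against background medians of 3.72 to 4.81. Its change as deposited was 0.20 ± 0.34. IL18, a cytokine of the interleukin-1 family, had a log2 fold change of -0.02 ± 0.10 (limma adjusted p = 0.988) although it was called lower as deposited, at -0.56. After median centring CXCL8, CCL20, IL1A and IL1B passed and CCL2 did not, at a log2 fold change of 1.66 ± 0.30 (limma adjusted p = 0.116).

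**Figure D2:**
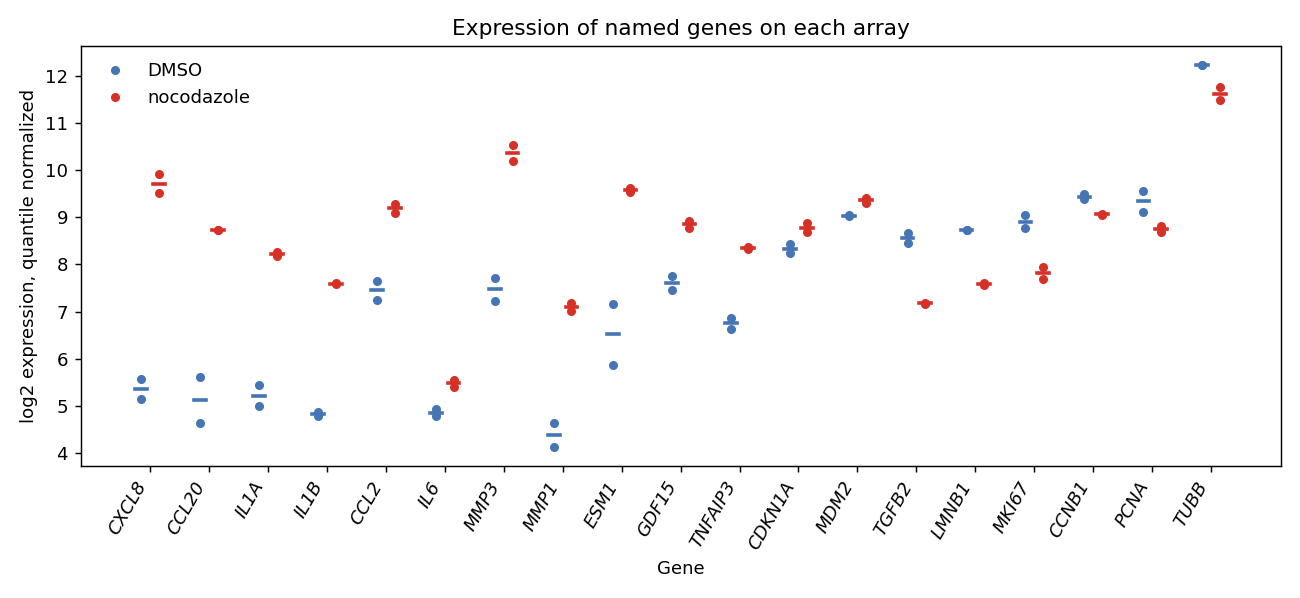
Log2 expression after quantile normalization (vertical axis) of 19 named genes (horizontal axis) on each array, with DMSO arrays in blue, nocodazole arrays in red and a bar at each group's mean. CXCL8 has the widest gap among the genes shown, with means of 5.36 and 9.72, while LMNB1 lies lower with nocodazole, at means of 8.72 and 7.58.

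Target and feedback genes of NF-kB, a transcription factor of inflammation, rose as a list too. Of 22 measured members 3 were called higher and 0 lower as deposited. On both scales 2 rose, 0 fell and 20 did not pass; 11 were higher and 0 lower when adjusted over the list alone. The median log2 fold change was 0.46, with a camera adjusted p of 8.69e-15 as deposited and 1.60e-16 after quantile normalization, and adjusted p = 0.152 with an estimated correlation. BCL2A1, an anti-apoptotic member of the BCL2 family, rose by 2.81 ± 0.40 (limma adjusted p = 0.0486), and its DMSO arrays spread widely, at 4.82 ± 1.03; DMSO replicate 2 lay below that array's background median, and with it raised to that median the change as deposited was 2.18. TNFAIP3, which encodes the NF-kB inhibitor A20, rose by 1.60 ± 0.13 (limma adjusted p = 0.00586). Haematopoietic markers moved the same way, with a median log2 fold change of 0.12 over 19 measured members. Camera gave them an adjusted p of 0.00499 as deposited and 0.0159 after quantile normalization (adjusted p = 0.585 and 0.476 with an estimated correlation). None of them passed the test on both scales; CD68, which encodes a lysosomal protein of macrophages and was named after its values were seen, was the 1 member called after quantile normalization, at 0.76 ± 0.11, both over all genes and when adjusted over the list alone. Without DMSO replicate 3 the haematopoietic list no longer passed camera, with an adjusted p of 0.255, and its median relative to all genes went from 0.17 to -0.05; that median was 0.29 without DMSO replicate 2 and 0.10 without dim genes.

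The SASP proteases and protease inhibitors rose as a list, with 3 of 15 measured members called higher on both scales and 3 called lower as deposited. After quantile normalization 4 were higher, 0 lower and 11 did not pass; 8 were higher and 1 lower when adjusted over the list alone. The median log2 fold change was 0.38, with a camera adjusted p of 4.25e-10 as deposited and 5.30e-11 after quantile normalization, and adjusted p = 0.152 with an estimated correlation. MMP3 (stromelysin-1) rose from 7.47 ± 0.35 to 10.36 ± 0.23 (SD, n = 2), a log2 fold change of 2.89 ± 0.18 (limma adjusted p = 0.00154). MMP1 (interstitial collagenase) rose from 4.38 ± 0.35 to 7.10 ± 0.11, a log2 fold change of 2.71 ± 0.20 (limma adjusted p = 0.00325); its DMSO replicate 2 lay below that array's background median, and with it raised to that median the change as deposited was 2.16. MMP9 (gelatinase B), named after its values were seen, rose by 0.90 ± 0.12 (limma adjusted p = 0.0376). ADAM9, a membrane-bound protease, was the member called lower as deposited with the largest change, and its log2 fold change was -0.31 ± 0.10 (limma adjusted p = 0.353). After median centring MMP1 passed, and MMP3 and MMP9 did not. MMP3 had a log2 fold change of 2.80 ± 0.41 there (limma adjusted p = 0.0501).

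The SASP growth factors and binding proteins had members on both sides. Of 32 measured, 4 were called higher and 7 lower as deposited. On both scales 2 rose (ESM1 and GDF15), 1 fell (TGFB2) and 29 did not pass; 8 were higher and 2 lower when adjusted over the list alone. The list's median log2 fold change was 0.28, and camera called it higher, with an adjusted p of 8.39e-05 as deposited and 6.56e-06 after quantile normalization, and adjusted p = 0.355 with an estimated correlation. The median relative to all genes was 0.23 as deposited and 0.15 without DMSO replicate 3. ESM1, which encodes the secreted proteoglycan endocan, rose by 3.07 ± 0.34 (limma adjusted p = 0.0216), from 6.51 ± 0.90 to 9.58 ± 0.06. GDF15, a stress-induced cytokine of the TGF-beta family and a p53 target, rose by 1.25 ± 0.14 (limma adjusted p = 0.0207). TGFB2, which encodes transforming growth factor beta 2, had a log2 fold change of -1.38 ± 0.12 (limma adjusted p = 0.00945). After median centring none of these 3 passed, although their log2 fold changes there were 2.92 ± 0.46, 1.18 ± 0.29 and -1.45 ± 0.28. The SASP shed receptors and surface proteins had a median of 0.32 over 13 measured members, 0 of which passed; 4 were higher and 1 lower when adjusted over the list alone. Relative to all genes that median was 0.33 as deposited and 0.11 without DMSO replicate 2. Camera did not call that list as deposited, with an adjusted p of 0.272, and called it higher after quantile normalization, with 0.00972 (adjusted p = 0.436 with an estimated correlation there).

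The G2/M and mitotic genes fell as a list. All 62 measured members were called lower as deposited, where the array-wide shift adds to each. After quantile normalization 4 fell (MKI67, CENPF, NDC80 and CCNA2, the last 3 named after their values were seen), 0 rose and 58 did not pass; 56 were lower and 0 higher when adjusted over the list alone. The list's median log2 fold change was -0.53, with a camera adjusted p of 2.15e-58 as deposited and 3.74e-50 after quantile normalization, and adjusted p = 0.152 with an estimated correlation. MKI67 went from 8.91 ± 0.20 to 7.81 ± 0.17 (SD, n = 2). NUSAP1, which encodes a spindle protein, went from 9.16 ± 0.26 to 8.16 ± 0.20, which did not pass (limma adjusted p = 0.0582), and CCNB1, which encodes the mitotic cyclin B1, had a log2 fold change of -0.37 ± 0.10 (limma adjusted p = 0.257).

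The DNA replication and S-phase genes fell as a list. All 48 measured members were called lower as deposited and 0 passed after quantile normalization, where all 48 had values under 0 and 31 were lower when adjusted over the list alone. The median log2 fold change was -0.43, with a camera adjusted p of 3.17e-37 as deposited and 1.02e-29 after quantile normalization, and adjusted p = 0.152 with an estimated correlation. The median relative to all genes was -0.46 as deposited and -0.30 without DMSO replicate 3. MCM6, a subunit of the replicative helicase, had a log2 fold change of -0.89 ± 0.13 (limma adjusted p = 0.0504), GINS2, a partner of that helicase, one of -0.89 ± 0.18 (limma adjusted p = 0.126), and PCNA, the sliding clamp of DNA polymerases, one of -0.59 ± 0.16 (limma adjusted p = 0.243). The homologous recombination and Fanconi genes fell as well, with a median of -0.31 over 17 measured members and a camera adjusted p of 6.22e-08 as deposited (adjusted p = 0.152 with an estimated correlation). As deposited 14 of them were called lower, after quantile normalization 0 passed, and 4 were lower when adjusted over the list alone. Their median relative to all genes was -0.31 as deposited and -0.57 without DMSO replicate 2. BARD1, a subunit of a DNA-repair ubiquitin ligase, had a log2 fold change of -0.69 ± 0.19 and HELLS, a chromatin-remodelling helicase, one of -0.87 ± 0.22 (limma adjusted p = 0.252 and 0.216).

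Nuclear and chromatin genes known to go down in senescent cells fell as a list. Of 15 measured, 14 were called lower and 0 higher as deposited. On both scales 2 fell (LMNB1 and NCAPD2), 0 rose and 13 did not pass; 9 were lower and 0 higher when adjusted over the list alone. The median was -0.41, with a camera adjusted p of 2.57e-15 as deposited and 6.12e-12 after quantile normalization, and adjusted p = 0.152 with an estimated correlation. Relative to all genes the median was -0.44 as deposited and ran from -0.64 without nocodazole replicate 3 to -0.27 without DMSO replicate 3. LMNB1 went from 8.72 ± 0.00 to 7.58 ± 0.04 (SD, n = 2), and NCAPD2, a subunit of condensin, had a log2 fold change of -0.79 ± 0.10 (limma adjusted p = 0.0319). HMGB2, a chromatin protein, had one of -0.29 ± 0.13, which did not pass (limma adjusted p = 0.526). The replication-dependent histone genes fell as a list, with a median of -0.17 over 34 measured members. As deposited 18 were called lower and 0 higher. On both scales 3 fell (H2AC21, H2BC14 and H1-4, the last named after its values were seen), 0 rose and 31 did not pass; 9 were lower when adjusted over the list alone. Their camera adjusted p was 0.000263 as deposited and 2.11e-07 after quantile normalization, with adjusted p = 0.152 with an estimated correlation. Their median relative to all genes was -0.20 as deposited, -0.40 without DMSO replicate 2 and -0.34 without dim genes. H2AC21 had a log2 fold change of -1.16 ± 0.11 (limma adjusted p = 0.0139) and H2BC14 one of -0.86 ± 0.11 (limma adjusted p = 0.0380).

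Other large falls were those of ZNF404, a zinc finger gene, with a log2 fold change of -1.48 ± 0.16 (limma adjusted p = 0.0207), FAM111B, which encodes a protease-like protein, with -1.39 ± 0.12 (limma adjusted p = 0.00586), and EDIL3, which encodes an integrin-binding matrix protein, with -1.08 ± 0.12 (limma adjusted p = 0.0207). SESN3, which encodes a sestrin, had a log2 fold change of -1.11 ± 0.19 (limma adjusted p = 0.0705), and MYCT1 one of 2.84 ± 0.52 (limma adjusted p = 0.0894), with a spread of 5.06 ± 1.38 between its DMSO arrays, the lower of which lay below its background median. Both were past the threshold as deposited and not after quantile normalization.

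**Figure D3:**
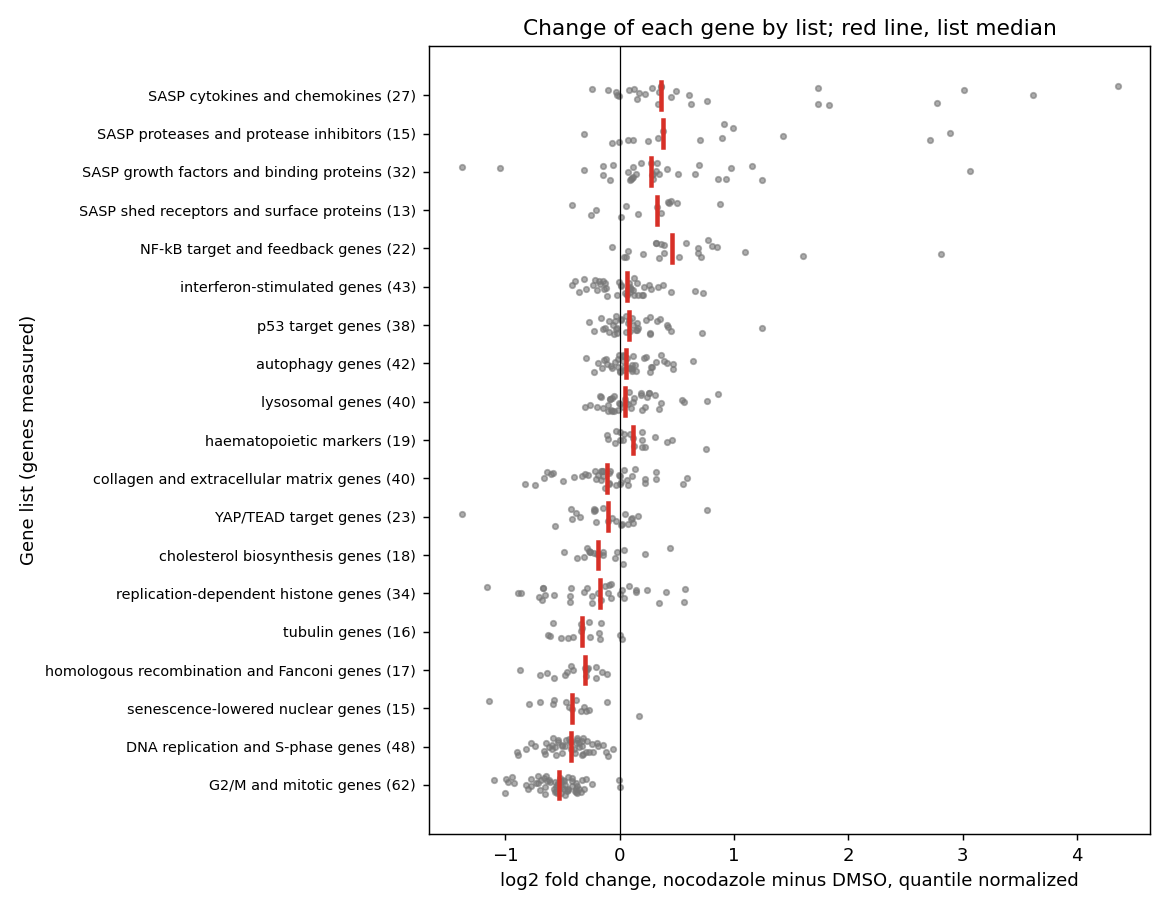
Log2 fold change after quantile normalization (horizontal axis, nocodazole minus DMSO) of each measured gene of 19 lists (vertical axis, number of genes in parentheses), with 1 grey point per gene and a red line at each list's median. The medians run from -0.53 for the G2/M and mitotic genes to 0.46 for the NF-kB genes; as deposited, the median change of all genes was -0.45.

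The genes of tubulin, the protein that nocodazole binds, fell as a list. The median log2 fold change was -0.33 over 16 measured tubulin genes and -0.37 over the 12 alpha- and beta-tubulin genes among them. As deposited 13 and 10 were called lower; after quantile normalization 0 passed in either list, and 8 and 6 were lower when adjusted over the list alone. Camera gave an adjusted p of 1.82e-07 for all tubulins as deposited (adjusted p = 0.152 with an estimated correlation) and 2.40e-06 for the alpha- and beta-tubulins (adjusted p = 0.155 with an estimated correlation). Relative to all genes both medians were -0.35 as deposited; without DMSO replicate 2 they were -0.53 and -0.56, and without DMSO replicate 3 they were -0.18 and -0.23. TUBB had a log2 fold change of -0.61 ± 0.10 (limma adjusted p = 0.0711), TUBA1B one of -0.45 ± 0.08 (limma adjusted p = 0.0786), TUBA1A one of -0.62 ± 0.12 (limma adjusted p = 0.111) and TUBB4B one of -0.58 ± 0.10 (limma adjusted p = 0.0786).

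Smaller shifts were found in matrix, YAP/TEAD and sterol genes. The YAP/TEAD targets, which respond to cell shape and contact, fell as a list with a median of -0.10 over 23 measured members. Camera gave them an adjusted p of 3.99e-05 as deposited and 0.00714 after quantile normalization (adjusted p = 0.152 and 0.310 with an estimated correlation). After quantile normalization, 222 of 10000 random lists of the same size and level had a median as low as theirs. As deposited 15 of the YAP/TEAD targets were called lower. TGFB2 was the 1 member that fell on both scales, 0 rose, and 1 was higher and 4 lower when adjusted over the list alone. The median relative to all genes was -0.10 as deposited, -0.36 without DMSO replicate 2, -0.04 without nocodazole replicate 2 and -0.20 without dim genes. CCN1 and CCN2, matricellular genes that YAP induces, had log2 fold changes of 0.01 ± 0.15 and -0.22 ± 0.17 (limma adjusted p = 0.996 and 0.831), and CCN1 was at -0.50 as deposited. RBMS3, an RNA-binding protein gene, had one of -0.57 ± 0.16 (limma adjusted p = 0.259). The collagen and extracellular matrix genes fell as a list with a median of -0.11 over 40 measured members. Camera gave them an adjusted p of 0.00104 as deposited and 0.00513 after quantile normalization (adjusted p = 0.478 and 0.306 with an estimated correlation). As deposited 19 were called lower. EFEMP1, which encodes a fibulin, was the 1 member that fell on both scales, with a log2 fold change of -0.82 ± 0.12 (limma adjusted p = 0.0486), and 2 were higher and 6 lower when adjusted over the list alone; THBS1, which encodes thrombospondin 1, had a log2 fold change of -0.74 ± 0.18 (limma adjusted p = 0.214). The cholesterol biosynthesis genes fell as a list with a median of -0.19 over 18 measured members. Camera gave them an adjusted p of 5.51e-05 as deposited and 0.0139 after quantile normalization (adjusted p = 0.152 and 0.401 with an estimated correlation). As deposited 14 of them were called lower, and 0 passed after quantile normalization, over all genes or adjusted over the list alone. Their camera call ended without DMSO replicate 3, at an adjusted p of 0.0910, and without dim genes, at 0.0707. Their median relative to all genes was -0.23 as deposited, -0.39 without DMSO replicate 2 and -0.01 without DMSO replicate 3. IDI1 and STARD4, an isoprenoid enzyme and a sterol carrier, had log2 fold changes of -0.49 ± 0.20 and -0.37 ± 0.23.

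The p53 targets did not move as a list on all scales. Of 38 measured, 1 was called higher and 13 lower as deposited. On both scales GDF15 rose, 0 fell and 37 did not pass; 2 were higher and 0 lower when adjusted over the list alone (GDF15 and GADD45A, the latter at 0.72 ± 0.12 and named after its values were seen). The list's median log2 fold change was 0.08, and relative to all genes it ran from -0.09 without DMSO replicate 2 to 0.22 without DMSO replicate 3. Camera gave an adjusted p of 0.423 as deposited, in the direction of a fall although the median relative to all genes was 0.04, and 0.00295 for a rise after quantile normalization (adjusted p = 0.289 with an estimated correlation there). CDKN1A, which encodes the cell-cycle inhibitor p21, had a log2 fold change of -0.07 ± 0.14 as deposited and 0.45 ± 0.12 after quantile normalization (limma adjusted p = 0.700 and 0.261). MDM2, which encodes the ubiquitin ligase of p53, had one of -0.19 ± 0.15 as deposited and 0.33 ± 0.10 after quantile normalization (limma adjusted p = 0.323 and 0.324). The sign of both genes depended on the scale. The 2 measured p53-linked long non-coding RNAs, too few for a list test, had a median of 0.08, and neither passed.

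Interferon-stimulated genes had a median log2 fold change of 0.07 over 43 measured members, and relative to all genes it ran from -0.03 to 0.10 with 1 array left out; 0 passed after quantile normalization or when adjusted over the list alone, and camera did not call the list as deposited (adjusted p = 0.150) or after quantile normalization (adjusted p = 0.503). Among the marker lists of cell types, that of the osteoblast lineage does not single out foreign cells, since U2OS is an osteosarcoma line. The osteoblast-lineage (13 measured), epithelial (17) and endothelial (11) markers had medians of -0.02, 0.01 and -0.03. Camera called none of them, with adjusted p of 0.949, 0.653 and 0.272 as deposited. Relative to all genes, with 1 array left out, these medians ran from -0.19 to 0.21, -0.06 to 0.09 and -0.05 to 0.16. When adjusted over the list alone, 2 osteoblast-lineage markers were higher and 2 lower, and 0 epithelial or endothelial markers passed. The autophagy (42 measured), lysosomal (40), glycolysis and hypoxia (30), ribosomal protein (46), ribosome biogenesis and MYC target (30) and BCL2 family genes (13) had medians of 0.05, 0.05, 0.10, 0.08, 0.10 and 0.14, and camera called them higher after quantile normalization and not as deposited. After quantile normalization their values were adjusted p = 0.351, 0.471, 0.653, 0.270, 0.477 and 0.359 with an estimated correlation. Except for the BCL2 family, camera's direction as deposited was down while the median relative to all genes was above 0. That sign was not stable: with 1 array left out these 5 medians ran from -0.07 to 0.14, -0.08 to 0.15, -0.09 to 0.24, -0.11 to 0.22 and -0.17 to 0.29, and that of the BCL2 family from -0.02 to 0.20. In these 6 lists BCL2A1 was the 1 gene that rose, and it and NPC1, a lysosomal cholesterol transporter at 0.86 named after its values were seen, were the 2 that passed when adjusted over the list alone.

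The oxidative phosphorylation (32 measured), NRF2 target (20) and SRF/MRTF and cytoskeletal genes (23) had medians of -0.07, -0.10 and -0.01; camera called them lower as deposited and not after quantile normalization, with adjusted p of 0.174, 0.0992 and 0.993 there. Relative to all genes, with 1 array left out, their medians ran from -0.26 to 0.05, -0.26 to 0.04 and -0.17 to 0.17. As deposited their values were adjusted p = 0.402, 0.270 and 0.355 with an estimated correlation. 0 of their members passed after quantile normalization, and when adjusted over the list alone 2 NRF2 targets were lower, the antioxidant enzyme gene NQO1 at -0.63 ± 0.12 and the malic enzyme gene ME1 at -0.55 ± 0.14. The unfolded protein and ATF4 response (35 measured) and heat shock genes (16) had medians of 0.06 and 0.00, with 0 members past the threshold after quantile normalization or adjusted over the list alone, and camera called neither list on either scale. With 1 array left out these medians relative to all genes ran from -0.11 to 0.23 and -0.27 to 0.17. Camera's direction as deposited was also opposite to the median relative to all genes for the SRF/MRTF, the unfolded protein and ATF4 and the osteoblast-lineage genes, at 0.00, 0.03 and -0.03, and with 1 array left out each of these 3 ran to both sides of 0. The small nucleolar RNA (251 measured) and microRNA genes (999) had medians of 0.04 and 0.04, and relative to all genes, with 1 array left out, these ran from -0.09 to 0.24 and 0.02 to 0.17; camera called both higher as deposited and neither after quantile normalization, with adjusted p of 0.152 and 0.289. As deposited both had adjusted p = 0.582 with an estimated correlation. As deposited 1 small nucleolar RNA was called higher and 51 lower, and 1 microRNA gene higher and 83 lower. After quantile normalization 1 small nucleolar RNA was higher, over all genes and when adjusted over the list alone, and 0 microRNA genes passed either way. The 1 was SNORD114-21, which lay below the background median on all 4 arrays, so it is called higher in the counts but not described as having risen. SNORD103C and MIR199A1 had log2 fold changes of -1.21 ± 0.26 and -1.27 ± 0.23 (limma adjusted p = 0.146 and 0.0899), and MIR222 one of 1.63 ± 0.26 (limma adjusted p = 0.0582); MIR199A1 lay below background on all 4 arrays, SNORD103C on 3 and MIR222 on both DMSO arrays.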

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

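The tests of the array-wide shift and of the cytokine genes were chosen only after those results were seen. The random-list tests of the cell-division genes were set out before their outcome was known.

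Rows with no gene symbol, which entered no gene test, also differed between the groups. The 64005 non-control rows from which they come held 62540 transcript clusters and 1465 rows of probe selection regions or junctions. As deposited, limma called 76 of 40906 higher and 2856 lower, and 18 higher and 3 lower also passed after quantile normalization. The largest rise after quantile normalization was 5.16 (TC04002067.hg.1; limma adjusted p = 0.000624) and the largest fall -2.78 (TC05003122.hg.1; limma adjusted p = 0.0337). 4 of the 18 had the same value, 2.22, and therefore do not count as separate signals. Both DMSO arrays lay below the background median for these 4 rows and for TC04002067.hg.1. With the DMSO values raised to that median, the changes as deposited were 0.05 for the 4 and 3.43 for TC04002067.hg.1. No biological explanation was tested.

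Lower values over nearly all genes on the nocodazole arrays were the first pattern. Arrays of the same treatment also differed. DMSO replicate 3 minus replicate 2 had a median of -0.27 over all genes, -0.61 over the ERCC rows and -0.39 over the background rows. Between the nocodazole arrays these medians were -0.14, -0.30 and -0.32. Over 10 bins by level, the DMSO difference ran from -0.55 to 0.11, against -0.37 to -0.51 for nocodazole minus DMSO. With 2 arrays per group, a shift tied to the treatment is not told apart from differences between arrays. The 155 ERCC control rows, which match no human gene, had a median change of -0.42, close to the -0.45 of all genes and beside -0.30 over 23 background rows. Lower brightness of the material labelled from the samples' RNA on the nocodazole arrays stays open all the same. Whether ERCC RNA was added is not given in the sources used here. Of the ERCC rows 44 lay below the background median on all 4 arrays and 87 above it, and without such RNA they would read cross-hybridisation. A single factor common to every probe of an array is argued against by the 4 hybridisation spike controls. So is lower brightness of all labelled material, these controls included. The controls had a median change of 0.066, from 0.04 to 0.14. Fewer human transcripts per amount of RNA, a biological possibility, stays open: the 4 poly-A spike controls had a median of -0.30 but ran from -0.68 to 0.05, and whether they were added is not given in the sources used here.

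The rise of cytokine, chemokine and metalloproteinase genes was the second. RNA from leukocytes is argued against as the whole cause by the haematopoietic markers, whose median change was 0.12 and upper quartile 0.21. Markers picked after their values were seen were PTPRC at 0.00, LYZ at 0.04, TYROBP at -0.03 and CORO1A at 0.09. On the other side, 15 of the 19 markers lay above 0, CD68 was called after quantile normalization at 0.76, and camera called the list higher on all 3 scales (adjusted p of 0.00499 as deposited, 0.0159 after quantile normalization and 0.0147 after median centring; adjusted p = 0.585 with an estimated correlation). The labels name only the cultured line U2OS and no leukocytes. The marker values by themselves do not exclude a small share of such RNA. After quantile normalization, 148 of 10000 random lists of the same size and level had a median as high as that of the haematopoietic markers. Of the 19 markers, 7, CD68 among them, had a mean level at or above the median of all genes, and 0 are in another list. A difference in scale between arrays is argued against by the fixed lists on the deposited values. Of 10000 random lists of the same size and level, the highest median was -0.24 against -0.06 for the SASP cytokines and chemokines, and -0.24 against -0.13 for the SASP proteases and protease inhibitors. A response of the cells to nocodazole is a hypothesis that remains, and differences in handling between the 2 groups of cultures were not tested.

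The fall of mitotic and DNA replication genes was the third. A trend of change with expression level was weighed with random lists after quantile normalization. That step leaves the medians of the 10 bins by level within 0.01 of 0, so these lists could not have shown such a trend. Of 10000 random lists of the same size and level, the lowest median was -0.11 against -0.53 for the G2/M and mitotic genes. It was -0.12 against -0.43 for the DNA replication and S-phase genes. As deposited, the bins' medians ran from -0.37 to -0.51, against -1.03 and -0.91 for the 2 lists. These deposited values argue against a level trend as the whole cause. Fewer cycling cells after nocodazole, or less of these transcripts per cell, may account for the fall, and arrays of whole cultures do not tell these apart. Both lists kept their direction and their camera call in 12 of 12 settings with the preset correlation, with adjusted p = 0.152 with an estimated correlation. Quantile normalization and median centring, which served to choose the lists, are among these settings.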

How the results depend on the processing

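Quantile normalization with the block or without dim genes, cyclic loess, and all counts on both scales were chosen only after the data were seen. Against 5392 genes called as deposited, 13334 were called with the replicate number as a block (127 higher, 13207 lower), 62 after quantile normalization, 37 with that and the block, 155 with that and without dim genes, 113 after cyclic loess, 20 after median centring, 1 without a variance trend, 2 by a per-gene test without moderated variance, 2514 at an adjusted p under 0.01 and 427 with a 2-fold minimum. Leaving out 1 array gave 1614 to 7845. Dim genes left out, the mean of all rows and a robust prior gave 5654, 5418 and 5394. Between-array scaling removes the downward shift by construction, and genes called lower went from 5341 to 21 after quantile normalization and 1 after centring. Removal of that shift alone would not reduce the genes called higher, which went from 51 to 41 and 19. The cause of this and of the other changes was not tested.

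Whether same-numbered arrays were made side by side is not given in the sources used here. The correlation of their deviations was 0.41 as deposited and 0.22 after quantile normalization, over 2 pairs. Among genes at or above the median level it was 0.42 after quantile normalization, so a pairing of the arrays is not excluded. With the block, 37 genes passed on both scales against 53 without, 34 of them shared. That count was 0 to 0 with 1 array left out, 123 without dim genes, 1 without a variance trend and 87 with cyclic loess, 52 of them shared. Over all rows, named or not, 6304 passed, against 18619 with the block and 733 to 5996 with 1 array left out.

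Camera called 20 lists as deposited and 0 with an estimated correlation, where 11 had an unadjusted p under 0.05. These settings differ in more than the correlation. For the SASP proteases after quantile normalization the estimated correlation was 0.0103, near the preset 0.01. Camera's adjusted p was 0.151 with it and 5.30e-11 with the preset. A call lost with an estimated correlation therefore does not show that correlation between genes accounts for the call. Fry, which tests a list without the other genes and so takes in the shift, called 1 list higher (SASP proteases) and 21 lower as deposited, and neither the SASP cytokines (adjusted p = 0.150) nor the NF-kB genes (0.130). After quantile normalization fry called the SASP cytokines (0.00285), SASP proteases (0.0193) and NF-kB genes (0.0376) higher and the histones (0.0213) lower, and not the G2/M (0.0587) or DNA replication genes (0.0607). The 15 lists called on all 3 scales kept their direction in 12 of 12 settings with the preset correlation and their call in each, except cholesterol (10) and haematopoietic (11). The 12 settings include quantile normalization and median centring, by which the 15 lists were chosen, so the calls there were fixed in advance. The haematopoietic median relative to all genes was -0.0494 without DMSO replicate 3 and ran to 0.286 without DMSO replicate 2.

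Scaling turned 3 named genes that lay below 0 as deposited. CCN1 was 0.00962 after quantile normalization and 0.0247 after cyclic loess. CDKN1A was 0.445, 0.351 after centring and 0.454 after cyclic loess. MDM2 was 0.326, 0.223 and 0.325. Over all settings of named genes, 530 values were the same, 278 lost the threshold, 4 gained it and 14 reversed.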

Other observations

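The single genes of this part were picked after their values were seen, and the tubulin test was chosen only after the tubulin genes were seen to be lower.

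Other genes among the 32 called higher on both scales were the following. IL24, which encodes a cytokine of the interleukin-10 family, rose by 2.33 ± 0.17 on the log2 scale after quantile normalization (limma adjusted p = 0.00275), and PI3, which encodes the elastase inhibitor elafin, by 1.94 ± 0.13 (limma adjusted p = 0.00210). IL1RL1, the receptor of interleukin-33, rose by 1.77 ± 0.25; its DMSO replicate 2 lay below that array's background median, and with it raised to that median the change as deposited was 0.92. IL13RA2, a decoy receptor of interleukin-13, and PTPN22, a phosphatase best known from lymphocytes, lay below background on both DMSO arrays and above it on both nocodazole arrays. With the DMSO values raised to the background median, their changes as deposited were 0.09 and 1.02. So raised, PNLIPRP3 and SPANXN4, also among the 32, changed by 0.11 and 0.12 as deposited. G0S2, an inhibitor of fat breakdown, rose by 1.36 ± 0.16, ITGA2, the collagen-binding integrin alpha 2, by 0.95 ± 0.11, and TM4SF1, a membrane protein of the tetraspanin type, by 0.91 ± 0.11. 2 long non-coding RNAs were among them, LINC00520 at 2.48 ± 0.13 (limma adjusted p = 0.000598) and UCA1 at 1.33 ± 0.14 (limma adjusted p = 0.0207). PTGS2, which encodes cyclooxygenase-2, was past the threshold after quantile normalization, at 1.31 ± 0.19 (limma adjusted p = 0.0486), and not as deposited (limma adjusted p = 0.0630).

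Among the 21 genes that fell, PCLAF, a partner of the clamp PCNA, had a log2 fold change of -0.91 ± 0.11 (limma adjusted p = 0.0294), HMGN2, a nucleosome-binding protein, one of -0.77 ± 0.10 (limma adjusted p = 0.0374), and TMPO, a lamina-associated protein, one of -0.81 ± 0.11 (limma adjusted p = 0.0486). The immediate-early and AP-1 genes had a median of 0.20 over 30 measured members, and relative to all genes one of 0.15 as deposited and 0.23 without nocodazole replicate 2. 0 passed after quantile normalization, where 9 were higher and 0 lower when adjusted over the list alone, among them DUSP5, a phosphatase of ERK, at 0.80 ± 0.14. Camera called that list after quantile normalization (adjusted p = 1.93e-07) and after median centring (0.000768), not as deposited (0.0611), with adjusted p = 0.297 with an estimated correlation after quantile normalization.

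Free tubulin is known to lower the stability of its own alpha and beta mRNAs, and nocodazole raises free tubulin, so a hypothesis was that the alpha- and beta-tubulin genes were lower than the other tubulins. The 12 alpha- and beta-tubulin genes had a mean log2 fold change of -0.36 ± 0.20 (SD) and the 4 gamma-, delta- and epsilon-tubulin genes one of -0.23 ± 0.17, a difference of -0.13. An exact two-sided permutation of the classes over 1820 arrangements gave p = 0.270. The difference was not detectable with these genes, and the hypothesis stays open.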
